A study of Mus musculus with 6 samples.

How the data were processed

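Lineage-negative cKit-positive cells were enriched with magnetic beads from marrow and spleen, at about 95% purity per the labels, and 400 ng of RNA went into each NEBNext Ultra library. The authors aligned reads with HISAT2 2.1.0, counted them per gene with HTSeq 0.6.1 and tested them with DESeq 1.18.0, per the labels. The labels name genome build mm39, but of the 54532 deposited genes a GRCm38 annotation held 54409, and 53499 had the same start and end, so positions are given as GRCm38. The deposited table holds raw counts per Ensembl gene, without normalisation, in 1 column for each of the 6 combinations of genotype and tissue. Column headers name the genotypes by letters, which were matched to the labels. The authors' table also holds the log2 fold change and the p-value of their own comparisons, which were counted at an adjusted p under 0.05. The 6 FPKM columns were not used, and neither were shorter tables that repeat values of the full one.

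The values were computed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr (minimum count 10), which left 18926, library sizes were scaled by TMM, and log2 CPM used a prior count of 2. The gene lists (550 of 568 list members measured, 32 lists with at least 5 of them), the comparisons, most alternatives and the rule for named genes were fixed before the data were examined. That plan foresaw values without a test if each group had 1 library, which was the case. After the layout was seen, genes were counted by a fixed size, at least 2-fold with a mean of at least 5 CPM over the libraries. Also after seeing the data, edgeR quasi-likelihood F tests with Benjamini-Hochberg adjustment over all genes were added in which libraries of other groups stand in for replicates: spleen against marrow with genotype as a block (2 residual degrees of freedom), knockouts against wild-type with tissue as a block (3 degrees of freedom), the knockouts as replicates within each tissue, and the difference of those effects (2 degrees of freedom). Such tests take the difference between MPL−/− and TPO−/− libraries, or between genotypes in their tissue effect, as the spread, so they do not measure variation between mice. The standard error of a log2 fold change was its size over the square root of F.

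A gene list is described by its median log2 CPM difference, by the members that passed the test over all genes or adjusted over the list alone, and by camera (preset correlation 0.01, and with an estimated correlation) and fry. The median's percentile among 10000 random lists drawn from 50 bins of mean expression was also computed. Named genes were Mpl and Thpo, the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the sides, leaving out pseudogenes and systematic names, and for each list the 2 to 4 members with the smallest adjusted p. For the comparison between the knockouts the rule was adapted to genes at least 2-fold apart in both tissues. Genes named outside this rule (Chrd, Kit, Pf4 and other markers given as CPM values) were chosen after their values were seen. Intervals of CPM values are 95% exact Poisson, also for a count of 0, and those of ratios are 95% exact binomial in the conditional form.

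The steps were tested on simulated data of the same layout. Of 100 genes changed 4-fold, 95 were called for knockouts over tissues, 98 between tissues, 84 within marrow, 82 within spleen and 37 for the difference of effects. Of 100 genes changed 2-fold, 41, 41, 11, 16 and 1 were called, with 2 to 5 false calls. In the simulated data 200 genes were changed. In the real data 560 genes in marrow and 678 in spleen were at least 2-fold apart between the MPL−/− and TPO−/− libraries. Those libraries stand in for replicates, so the simulated numbers of recovered and false calls cannot be carried over to the real tests. The alternatives were size factors of DESeq2, total counts, other filters on low counts, another prior count, removal of globin, immunoglobulin and mitochondrial genes, DESeq2 and limma-voom tests, models without the block or with a term for the knockout label, and leaving out each library.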

Results

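RNA was sequenced from haematopoietic stem and progenitor cells of young mice, taken as lineage-negative cKit-positive cells from bone marrow and from spleen. Wild-type mice (2 animals), TPO−/− mice (3 animals), which lack thrombopoietin, and MPL−/− mice (3 animals), which lack its receptor, were compared at 3 to 4 months of age. The deposited table held 1 library for each genotype and tissue, 6 in all, and the labels do not say whether RNA of several mice was combined in it. No value therefore has a replicate of its own genotype and tissue, and confidence intervals cover counting error only. The total counts were 18666875 in wild-type marrow, 23726165 in MPL−/− marrow, 24357221 in TPO−/− marrow, 18382141 in wild-type spleen, 15741048 in MPL−/− spleen and 21801883 in TPO−/− spleen. After the filter on low counts 18926 genes were kept, of which 11152 had a mean of at least 5 CPM (TMM-normalised, as are all CPM values given). Gene positions are those of the deposited table, which match genome build GRCm38.

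The first question was whether the deleted genes could be seen in the counts. Mpl (ENSMUSG00000006389, chromosome 4, 118442415 to 118457513), the thrombopoietin receptor, stood at 31.0 CPM in wild-type marrow and 10.1 CPM in wild-type spleen. In the libraries labelled MPL−/− it was still read, at 23.4 CPM in marrow, 0.755 times the wild-type level (95% exact binomial interval 0.671 to 0.85), and at 16.4 CPM in spleen, 1.63 times (1.35 to 1.98). In the libraries labelled TPO−/− it stood at 3.61 CPM in marrow, 0.116 times the wild-type level (0.0917 to 0.146), and at 0.135 CPM (3 reads) in spleen, 0.0134 times (0.00275 to 0.0399). Thpo (ENSMUSG00000022847, chromosome 16, 20724454 to 20734511), the gene of thrombopoietin, had 0 reads in the wild-type and MPL−/− libraries, and 2 and 11 reads in the marrow and spleen libraries labelled TPO−/−. A count of 0 allows up to 0.233 CPM in the shallowest of these libraries, MPL−/− spleen (upper end of the 95% exact Poisson interval). Chrd (ENSMUSG00000006958), which overlaps Thpo on the opposite strand and was looked at after its values were seen, had 17 and 26 reads in those TPO−/− libraries and 0 in the other 4. Since Mpl runs against the labels, each direction drawn for a single knockout below rests on the label of its library, and the comparisons of both knockouts with wild-type do not depend on which knockout label is which.

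**Figure D1:**
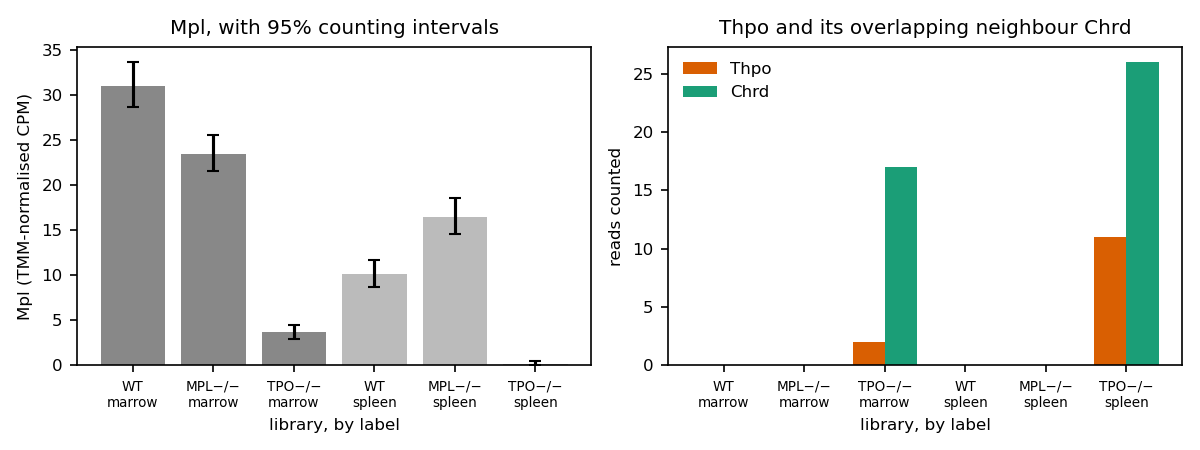
Left, Mpl level in TMM-normalised CPM in each of the 6 libraries by label, with 95% exact counting intervals as error bars (dark bars marrow, light bars spleen): 31.0 CPM in wild-type marrow, and 3.61 and 0.135 CPM in the libraries labelled TPO−/−. Right, reads counted for Thpo and the overlapping gene Chrd, which were above 0 in the TPO−/− libraries alone.

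Spleen and marrow were compared over the 3 genotypes, to ask how the same gate differs between the organs. Genes of T and NK cells, macrophages and antigen presentation by MHC class II were higher in spleen, and genes of granulocytes and cell division were higher in marrow. By size of fold alone, 1166 genes were at least 2-fold higher and 925 at least 2-fold lower in spleen on the mean over genotypes, and 757 and 270 did so in each of the 3 genotypes. Without wild-type marrow these means gave 1046 higher and 1077 lower, and without wild-type spleen 1467 and 1407. In wild-type mice alone the counts were 1075 higher and 419 lower. In the libraries labelled MPL−/− they were 1374 and 1476, and in those labelled TPO−/− 1285 and 1533. Which direction had more genes in the knockouts depended on the scaling, since size factors of DESeq2 gave 1528 and 1217 in MPL−/− and 1382 and 1383 in TPO−/−, against 1069 and 430 in wild-type. The edgeR tests given from here on were chosen after the data were seen. A quasi-likelihood test in edgeR that took the genotypes as replicates called 1875 genes higher and 1363 lower in spleen at an adjusted p under 0.05. Of these 3238 genes, 2542 had no overlap between the 3 spleen and the 3 marrow libraries, which 10% of unselected genes would show by chance. The genes were called from the same libraries, which favours separated values, so that share cannot be used to judge the calls. The number of calls depended on the libraries: 6898 without wild-type marrow, 672 without MPL−/− marrow, 6252 without wild-type spleen and 557 without MPL−/− spleen. More genes were lower than higher without wild-type marrow (3068 higher, 3830 lower) and without wild-type spleen (3069 higher, 3183 lower).

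The gene with the largest fitted rise was Dapl1 (ENSMUSG00000026989, chromosome 2, 59484653 to 59505020), listed at 0 in all 3 marrow libraries and at 0.710, 9.09 and 24.1 CPM in wild-type, MPL−/− and TPO−/− spleen. Adam23 rose by a log2 fold of 8.63 ± 0.60 (SE; adjusted p = 0.000605) and Apol7c by 8.63 ± 0.24 (adjusted p = 0.000117). Adamdec1, Tlr11, C6, Il12b, Gpr141b, Igkv8-16 and Igkv9-123 followed, with log2 folds from 7.84 down to 6.72. Il12b, a subunit of interleukin 12, went from at most 0.126 CPM in marrow to 9.78, 19.0 and 6.39 CPM in spleen. Among the falls, Igll1 (ENSMUSG00000075370, chromosome 16, 16860671 to 16863985), part of the pre-B cell receptor, went from 3.11, 52.9 and 137 CPM in marrow to at most 0.315 CPM in spleen. Col1a1, a chain of type I collagen, fell by 7.96 ± 0.35 (adjusted p = 0.000254), and Cxcl12, the chemokine that holds stem cells in marrow, fell by 7.04 ± 0.49 (adjusted p = 0.000605). Fcnb, Lin28a, Vpreb1, Prom1, Camp, Col1a2 and Rhou came next, with log2 folds from −6.90 to −6.10.

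All 13 macrophage genes rose in spleen, with a median log2 fold of 2.86, among them the complement genes C1qa (3.65 ± 0.22, adjusted p = 0.000481) and C1qc (3.26 ± 0.23) and Spic, a factor of red-pulp macrophages (4.47 ± 0.32). Of 18 T and NK cell genes 17 rose (median 4.16), led by Tcf7 (5.01 ± 0.19, adjusted p = 0.000254) and Cd3e (5.59 ± 0.25), and Nkg7 did not pass. All 7 MHC class II genes rose (median 4.17), as did 7 of 10 MHC class I genes (median 0.84), with H2-Ab1 at 4.17 ± 0.34 and Nlrc5 at 1.83 ± 0.21. Of 10 dendritic cell genes 5 rose, Xcr1 by 5.57 ± 0.37 and Itgax by 3.08 ± 0.21. Of 11 innate lymphoid genes 7 rose, among them Il18r1 (3.54 ± 0.22) and Cxcr6 (3.91 ± 0.30). The interferon list had 10 rises in 23 genes, led by Gbp2 (1.95 ± 0.20) and Ifit3 (3.56 ± 0.45), and the NF-kB and inflammation list 7 in 14, led by Relb (2.40 ± 0.23) and Nfkb2 (1.35 ± 0.16). None of these lists had a fall. B cell genes went both ways, with 4 rises, 3 of them immunoglobulin constant genes such as Iglc2 (4.41 ± 0.32) and Ighm (3.27 ± 0.39), and 3 falls in the early B cell genes Igll1, Vpreb1 and Vpreb3.

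All 20 mitosis genes fell in spleen (median −1.50), among them Ccnb1 (−1.67 ± 0.18, adjusted p = 0.00235) and Aurka (−1.45 ± 0.20), and 19 of 20 DNA replication genes fell (median −1.15), led by Rrm2 (−1.52 ± 0.21). Of 19 granulocyte genes 13 fell, with a median of −5.31, including the granule enzymes Prtn3 (−5.17 ± 0.67, adjusted p = 0.00443), Ctsg (−5.03 ± 0.66) and Mpo (−5.04 ± 0.67). Mpo stood at 3950 CPM in wild-type marrow and 336 CPM in wild-type spleen. These means over genotypes were larger than the difference in wild-type alone. The granulocyte median was −1.60 in wild-type, −5.30 in MPL−/− and −7.56 in TPO−/−. For mitosis genes the medians were −0.913, −1.815 and −1.817, and for DNA replication genes −0.515, −1.444 and −1.274, in the same order. Of 23 erythroid genes 8 fell, led by Gypa (−1.65 ± 0.21) and Tfrc (−1.20 ± 0.16), of 12 haem synthesis genes 5, led by Tfrc and Abcb10 (−1.11 ± 0.19), and of 18 glycolysis and hypoxia genes 8, led by Egln3 (−2.94 ± 0.26) and Pgam1 (−1.97 ± 0.22). Of 17 stem cell genes Ly6a rose (2.37 ± 0.32) and 3 fell (Mecom, Hoxa9 and Hlf). Of 22 megakaryocyte genes Nbeal2 rose and 4 fell (Itga2b, Pf4, Thbs1 and Selp), and of 11 monocyte genes Csf1r rose and 4 fell (Ly6c2, F13a1, Ccr2 and Lyz2). The stroma and endothelium list had 1 rise, Stab2 of sinus endothelium (2.37 ± 0.28), and 3 falls in Col1a1, Cxcl12 and Col1a2. Kit, the receptor of the gate, stood at 402 CPM in wild-type marrow and 476 CPM in wild-type spleen, and immunoglobulin genes took 3.82% of the counts in wild-type spleen against 1.29% in wild-type marrow. Adjusted over the list alone, 19 granulocyte genes, 20 DNA replication genes and 20 mitosis genes fell, and 17 T and NK cell genes rose. A camera test with a preset correlation called 18 of 32 lists, none of which held with an estimated correlation (lowest adjusted p = 0.126, for T and NK cell genes), and fry, which asks whether a list moves one way, called 7.

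**Figure D2:**
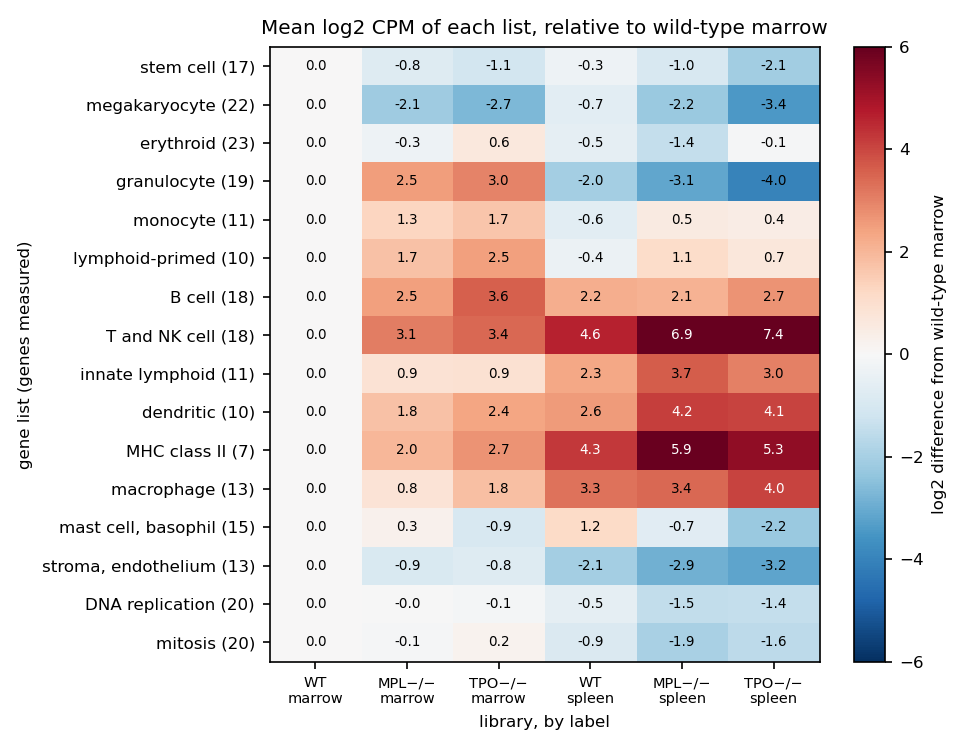
Mean log2 CPM of 16 gene lists (vertical axis, genes measured in brackets) in each of the 6 libraries by label (horizontal axis), as the difference from wild-type marrow in log2 units, printed in each cell and coloured on a scale that ends at −6 and 6. Megakaryocyte genes were lower in all knockout libraries than in wild-type of the same tissue, and granulocyte genes were higher in knockout marrow and lower in knockout spleen.

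Both knockouts were then set against wild-type, which asks what the loss of the thrombopoietin signal changes in the gate. T and NK cell genes were higher over both tissues, and part of the megakaryocyte genes and several regulators of the red cell lineage were lower. On the mean over tissues 1201 genes were at least 2-fold higher and 495 at least 2-fold lower. An edgeR quasi-likelihood test with a term for tissue, 4 knockout against 2 wild-type libraries, called 963 genes higher and 439 lower. It counted the marrow and spleen libraries of a genotype as separate replicates, though they may come from the same mice. A difference between these groups of mice other than genotype would therefore be called as well. Of those 1402 genes 930 had no overlap between knockout and wild-type libraries, against 13.3% of unselected genes by chance. These genes too were called from the same libraries, so that share cannot be used to judge the calls. The count was 783 without MPL−/− marrow, 677 without TPO−/− marrow, 102 without wild-type spleen, 161 without MPL−/− spleen and 546 without TPO−/− spleen. Without wild-type marrow, which leaves the contrast to spleen, 719 genes were higher and 880 lower in the test, so that called rises did not outnumber falls without that library, while by size of fold 804 were higher and 630 lower. The knockout effects in marrow and spleen had a Pearson r of 0.547 and a Spearman rho of 0.56 across 11152 genes, with the same sign in 70.7%. They share no library, but both organs of a genotype may come from the same mice. Differences between the groups of mice other than genotype could then enter both effects, and genes are not independent replicates.

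The largest fall was that of Tubb1 (ENSMUSG00000016255, chromosome 2, 174450695 to 174457882), the platelet form of beta-tubulin, with a log2 fold of −6.40 ± 0.74 (adjusted p = 0.0137). It went from 15.0 CPM to 0.386 and 0.210 CPM in MPL−/− and TPO−/− marrow and from 27.1 CPM to 0.379 and 0 CPM in spleen. Ppbp (ENSMUSG00000029372, chromosome 5, 90768518 to 90770063), a platelet chemokine, fell by 5.19 ± 0.79 (adjusted p = 0.0172). Robo3, Thbs1, Mmrn1, Ltbp1, Gp5, Zg16, Ptpn14 and Shank3 followed, with log2 folds from −3.39 to −2.61. Ptpn14 went from 122 CPM in wild-type spleen to 24.1 and 9.59 CPM in the knockout spleens. The largest rise was that of Slamf6 (ENSMUSG00000015314, chromosome 1, 171917515 to 171953170), a lymphocyte surface receptor, by 3.65 ± 0.65 (adjusted p = 0.0236), from 2.21 to 27.0 and 83.0 CPM in marrow and from 11.5 to 65.8 and 112 CPM in spleen. Cd209a, a lectin of dendritic cells, rose by 3.50 ± 0.44 (adjusted p = 0.0138), and Pacsin1, Cd300lf, Fgf13, Slfn2, Rflnb, St8sia1, BC043934 and Cd300c by 3.46 to 2.85.

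Of 22 megakaryocyte genes 11 fell and 1 rose (median −2.31), and 16 fell and 2 rose when adjusted over the list alone. Gfi1b, a regulator of the platelet lineage, fell by 1.76 ± 0.16 (adjusted p = 0.0129) and Gp5, a platelet glycoprotein, by 2.82 ± 0.38 (adjusted p = 0.0146), and the rise was in Nbeal2, of platelet granules (1.07 ± 0.19). Pf4, platelet factor 4, did not pass (adjusted p = 0.0687) but stood at 113 CPM in wild-type marrow against 14.7 and 3.07 CPM, and at 24.3 CPM in wild-type spleen against 7.13 and 0.495 CPM. Of 23 erythroid genes 8 fell, among them the transcription factors Klf1 (−1.48 ± 0.15, adjusted p = 0.0129), Gata1 (−1.73 ± 0.18) and Tal1 (−1.36 ± 0.16) and the erythropoietin receptor Epor (−1.37 ± 0.18), and of 12 haem synthesis genes Alad alone (−0.86 ± 0.15). Of 17 stem cell genes 2 fell, Tek (−2.64 ± 0.48, adjusted p = 0.0245) and Mmrn1 (−3.09 ± 0.71, adjusted p = 0.0472), and 15 of the 17 were lower on the mean over tissues (list median −0.79). Gata2 and Meis1 did not pass, with Meis1 at 41.4 CPM in wild-type marrow against 23.7 and 11.3 CPM and at 34.7 CPM in wild-type spleen against 8.84 and 3.15 CPM. Kit stood at 402 CPM in wild-type marrow against 285 and 202 CPM, and at 476 CPM in wild-type spleen against 275 and 103 CPM, and did not pass (adjusted p = 0.13).

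Of 18 T and NK cell genes 17 rose (median 2.95), led by Tcf7 (2.80 ± 0.23, adjusted p = 0.0129), Thy1 (2.97 ± 0.27) and Cd3e (3.59 ± 0.30). Cd3e stood at 0.263 CPM in wild-type marrow against 4.42 and 4.75 CPM, and at 19.4 CPM in wild-type spleen against 162 and 257 CPM. Gzmb, a killer cell protease, went the other way without passing over all genes, from 186 CPM in wild-type spleen to 76.1 and 33.4 CPM. Of 10 lymphoid-primed genes 4 rose, Dntt (2.17 ± 0.30), Notch1 (1.16 ± 0.18), Il7r (3.28 ± 0.52) and Ccr9 (2.65 ± 0.46). Of 11 monocyte genes 6 rose, led by Ly6c2 (2.21 ± 0.21) and Ccr2 (2.03 ± 0.27), of 10 dendritic genes 4, led by Itgax (1.92 ± 0.21), of 7 MHC class II genes 3, led by H2-Ab1 (1.95 ± 0.32), of 10 MHC class I genes 2, Psmb9 and Nlrc5, and of 13 macrophage genes 2, Cd68 and Vcam1. Innate lymphoid genes had 4 rises and a fall in Il1rl1 (−1.93 ± 0.26), niche and adhesion genes 4 rises (Selplg, Itgal, Sell and Cxcr4), and JAK-STAT genes 3 rises (Socs1, Ccnd1 and Sh2b3) and a fall in Stat5a (−0.84 ± 0.19). The NF-kB and inflammation list had 4 falls, led by Tnfaip3 (−1.19 ± 0.15), and 2 rises, and the stroma and endothelium list 2 falls, Cxcl12 (−3.11 ± 0.42) and Plvap (−1.56 ± 0.28). Xist fell by 1.02 ± 0.17 and Eif2s3y on the Y chromosome rose by 0.97 ± 0.16, while reads of both were present in all 6 libraries. Xist stood at 726 and 613 CPM in wild-type marrow and spleen and between 287 and 406 CPM in the knockout libraries. The Y-linked Kdm5d was also higher in each knockout library than in wild-type of the same tissue, but Ddx3y and Uty were not. A different mix of male and female cells in the knockout libraries therefore cannot be told apart from genotype.

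In the other lists at most 2 genes a direction passed over all genes. These were granulocyte (Gfi1 up), B cell (Igll1 up), quiescence (Foxo1 and Txnip up), immediate early (Klf2 up, Nr4a1 down), interferon (Mx1 and Stat1 up), BMP and stress erythropoiesis (Id2 up), mitochondrially encoded (mt-Nd3 up), cholesterol synthesis (Mvd up) and glycolysis and hypoxia (Pfkp and Pkm up, Hk1 down). The ribosomal protein list had a rise in Rps6ka1, a kinase caught by its symbol, and a fall in Rps12. DNA replication, mitosis, mast cell and basophil, p53 and oxidative phosphorylation genes had no gene past the threshold in either direction. Atp5b of oxidative phosphorylation stood at 1570 CPM in wild-type marrow against 1270 and 1040 CPM, with an adjusted p of 0.0675. A camera test with a preset correlation called 19 of 32 lists, none with an estimated correlation (lowest adjusted p = 0.273), and fry called 7.

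**Figure D3:**
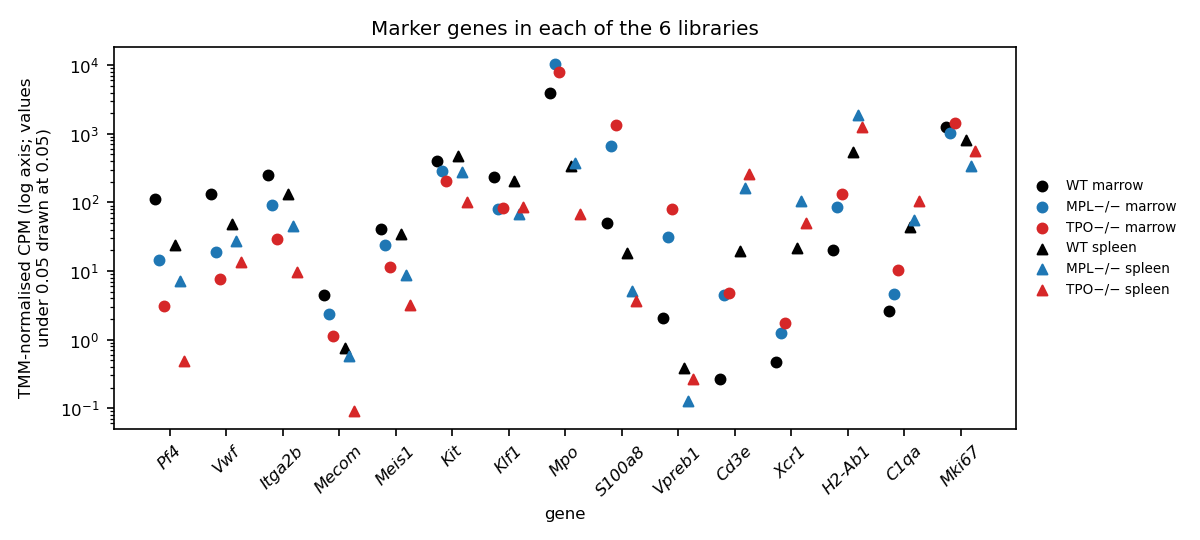
Level of 15 marker genes (horizontal axis) in TMM-normalised CPM on a log axis, 1 point per library by label (circles marrow, triangles spleen, black wild-type, blue MPL−/−, red TPO−/−), without replicates. Pf4 was at 113 CPM in wild-type marrow and at 0.495 CPM in TPO−/− spleen, and Cd3e at 0.263 CPM in wild-type marrow and 257 CPM in TPO−/− spleen.

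In marrow alone, by size of fold, neutrophil granule genes and most B cell and T cell genes were higher in both knockouts than in wild-type, and most megakaryocyte genes lower. At least 2-fold higher were 1089 genes in MPL−/− and 1412 in TPO−/− marrow, and at least 2-fold lower 383 and 629. In both knockouts together 962 genes were higher and 316 lower by that size. All 19 granulocyte genes were at least 2-fold higher in both, with list medians of 2.29 in MPL−/− and 3.15 in TPO−/− marrow. S100a8 went from 50.5 to 656 and 1360 CPM, Mpo from 3950 to 10300 and 7960 CPM, and Fcnb from 6.01 to 109 and 195 CPM. Of 18 B cell genes 14 were at least 2-fold higher in both knockouts (medians 3.45 and 4.89), among them Vpreb1, from 2.06 to 31.0 and 80.6 CPM, and Cd79a, from 13 to 99.1 and 268 CPM, while Jchain of plasma cells went from 1100 to 380 and 97.5 CPM. Of 22 megakaryocyte genes 17 were at least 2-fold lower in both (medians −1.80 and −2.74), with Vwf at 131 CPM against 18.9 and 7.52 CPM.

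When MPL−/− and TPO−/− marrow were taken as replicates, edgeR called 116 genes higher and 58 lower. The variation of the lone wild-type library was not measured and was assumed to be like that of the knockouts, so these calls and those by list below hold for this library only. All called genes lacked overlap between the sides, as 66.7% of unselected genes would by chance with 2 libraries against 1. They were called from the same libraries. The count was 1066 without MPL−/− marrow, 300 without TPO−/− marrow, 102 without wild-type spleen, 0 without MPL−/− spleen and 0 without TPO−/− spleen, since the spread is shared with spleen. The largest named rises were in T and NK cell genes that had 1 or 2 reads in wild-type marrow: Trac was at 0.0527 CPM against 6.74 and 5.92 CPM, and Klre1, Tcrg-C2 and Fasl followed. Cd300lf stood at 0.685 CPM against 16.3 and 30.5 CPM (log2 fold 5.08 ± 0.65, adjusted p = 0.0415), and Chil3 at 15.7 CPM against 222 and 455 CPM (4.43 ± 0.50, adjusted p = 0.0412). Immunoglobulin variable genes led the lower side. Igkv1-99 (−8.75 ± 1.2) differed by more than any named rise, at 195 CPM in wild-type marrow against 0.858 and 0.042 CPM, and Ighv1-69 was at 84.0 against 3.65 and 2.81 CPM. Cxcl12 was at 107 CPM in wild-type marrow against 10.6 and 8.99 CPM (−3.44 ± 0.39, adjusted p = 0.0412), and Igsf3 at 35.0 CPM against 6.27 and 4.20 CPM (−2.74 ± 0.34, adjusted p = 0.0415). By list, 9 granulocyte genes and 7 T and NK cell genes were higher and 4 erythroid genes (Klf1, Aqp1, Epor and Gata1) and 3 megakaryocyte genes (Gfi1b, Clec1b and Itgb3) lower past the threshold. No B cell gene passed (lowest adjusted p = 0.0513, for Vpreb1). The calls also depended on the processing. With limma-voom lower genes outnumbered higher ones, with DESeq2 or without the filter many more genes were called, and with a filter of 1 CPM in 2 libraries none was. Camera called 16 lists with a preset correlation and 0 with an estimated one (lowest adjusted p = 0.395), and fry called 0 (lowest adjusted p = 0.242).

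In spleen, T and NK cell genes were higher in both knockouts, and DNA replication genes were lower. At least 2-fold higher were 1368 genes in MPL−/− and 1370 in TPO−/− spleen, and 1090 and 1270 were at least 2-fold lower. In both knockouts 996 were higher and 765 lower by that size. Of 18 T and NK cell genes 16 were at least 2-fold higher in both (medians 2.48 and 3.11), with Cd8b1 at 9.45 CPM against 144 and 282 CPM. All 20 mitosis and all 20 DNA replication genes were lower on the mean of the knockouts (medians −0.88 and −0.98), with Mki67 at 800 CPM against 344 and 560 CPM and Mcm7 at 465 CPM against 213 and 199 CPM. Of 15 mast cell and basophil genes 11 were at least 2-fold lower in both (medians −1.67 and −3.83), with Gata2, shared with the stem cell list, at 293 CPM against 70.8 and 11 CPM. The stem cell median was −0.17 in MPL−/− and −2.20 in TPO−/− spleen, and the granulocyte median −0.90 and −2.21.

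With the knockout spleens as replicates, edgeR called 721 genes higher and 965 lower, again against a lone wild-type library that was assumed to vary like the knockouts. All called genes lacked overlap, against 66.7% of unselected genes by chance, but they were called from the same libraries. The count was 359 without MPL−/− spleen and 0 without TPO−/− spleen. Which direction had more genes was not stable: 719 were higher and 655 lower with size factors of DESeq2, 1659 and 1373 with the DESeq2 test, 1241 and 1110 with the spleen libraries alone in the fit, and 200 and 159 without MPL−/− spleen. Slc16a5, a monocarboxylate transporter, stood at 0.983 CPM against 17.5 and 30.7 CPM (log2 fold 4.61 ± 0.60, adjusted p = 0.0253), and Dapl1, Cd8b1, Tmie, Cd6, Tdrp, Cd3d, Zfp683, Cd209a and Slc6a19 were next, from 4.54 to 3.72. Tubb1 led the lower side (−7.30 ± 1.0, adjusted p = 0.0253), followed by Smtnl2, Ppbp, Thbs1, Mmrn1, Cxcl2, Robo3, Dnah12, Col1a2 and Ltf. By list, 15 T and NK cell genes, 5 lymphoid-primed genes, 4 monocyte genes and 3 of 10 dendritic genes (Itgax, Clec9a and Cd209a) were higher past the threshold, and 14 DNA replication genes (such as Dtl, −1.62 ± 0.21), 9 mitosis genes, 7 granulocyte, 7 erythroid, 6 megakaryocyte and 6 NF-kB and inflammation genes lower. Gfi1 (1.33 ± 0.20), Nbeal2 and Icam1 of the granulocyte, megakaryocyte and NF-kB lists passed as higher. Of the mast cell and basophil genes 2 were lower past it (Mcpt4 and Tpsb2), and of the stem cell genes 2 (Mmrn1 and Tek). Ly6a, which encodes the stem cell antigen Sca-1, was higher (1.65 ± 0.24, adjusted p = 0.0265), at 34.0 CPM in wild-type spleen against 110 and 103 CPM. Camera called 21 lists with a preset correlation and 0 with an estimated one (lowest adjusted p = 0.481), and fry called 0 (lowest adjusted p = 0.084).

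Whether the knockout effect differed between the organs was asked next. Granulocyte and B cell genes stood apart most: their knockout effect was lower in spleen than in marrow by a median log2 of −3.86 (19 of 19 genes) and −3.93 (14 of 18 genes). DNA replication (−0.92), mitosis (−0.98) and immediate early genes (−0.98) were also lower, in 20 of 20, 20 of 20 and 15 of 18 genes. By size, 585 genes had a knockout effect at least 2-fold higher in spleen and 1091 at least 2-fold lower. The test that follows took no account of the knockout label that a marrow and a spleen library share. With a term for that label genes were called, more of them lower than higher, so the absence of calls depends on the model. In the test of the difference itself, edgeR called 0 genes, with 2089 at an unadjusted p under 0.05. DESeq2 called 322 and limma-voom 0, and edgeR called 131 without MPL−/− marrow and 9 without TPO−/− marrow. Adjusted over the list alone, 13 granulocyte, 12 B cell, 13 DNA replication and 9 mitosis genes were lower, and 2 B cell genes higher. Camera called 8 lists with a preset correlation, none with an estimated one (lowest adjusted p = 0.75), and fry 0 (lowest adjusted p = 0.171).

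The knockouts were last compared with each other, by label and with 1 library a side, so that only values are given. MPL−/− marrow had 217 genes at least 2-fold higher and 343 lower than TPO−/− marrow, MPL−/− spleen 476 higher and 202 lower than TPO−/− spleen, and 118 and 78 did so in both tissues. Without globin, immunoglobulin and mitochondrial genes 127 in place of 217 were higher in marrow. Mpl itself headed the genes higher in the libraries labelled MPL−/−, by a mean log2 fold of 4.41. Epx and Prg3, granule proteins of eosinophils, were next outside the immunoglobulin genes, with Epx at 76.7 against 15.8 CPM in marrow and 6.95 against 0.090 CPM in spleen. Pf4, Myct1, Hspa1a and Hmga1b came after. Baiap3 (ENSMUSG00000047507, chromosome 17, 25242659 to 25256364) headed the genes lower in the libraries labelled MPL−/−, at 0.129 against 12.7 CPM in marrow and 1.89 against 75.7 CPM in spleen, and Apol11b, Camk2b, Vmn2r97, Fn3k, Cpm and Ndufs5 followed. Baiap3 lies in the stretch of chromosome 17 described further below. The lower Ndufs5 level went with more reads of its pseudogene BC002163 (28.0 and 16.2 CPM in MPL−/− marrow and spleen), so a lower expression of Ndufs5 is not settled. Hba-a1 stood at 958 against 5360 CPM in marrow and 353 against 2270 CPM in spleen, and Hba-a2 and Hbb-bt differed the same way. Megakaryocyte genes had a median 0.47 higher in MPL−/− than TPO−/− marrow and 1.13 higher in spleen, stem cell genes 0.06 and 1.46, and mast cell and basophil genes 1.46 and 1.81. Macrophage genes had medians of −1.08 and −0.66, erythroid genes −0.76 and −1.27, and B cell genes −1.49 and −0.74.

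The authors' deposited table held their own comparisons, made with DESeq per the labels and counted here at an adjusted p under 0.05. It gave 2045 genes between wild-type spleen and marrow (1433 higher in spleen), 1438 between both knockout marrows and wild-type marrow (1014 higher) and 2220 between both knockout spleens and wild-type spleen (1301 higher). For single libraries the authors' deposited table gave 1591 genes in MPL−/− and 2747 in TPO−/− marrow, and 3848 in MPL−/− and 4239 in TPO−/− spleen, each against wild-type of the same tissue. Between the knockouts it gave 464 genes in marrow and 1153 in spleen. The comparisons between single libraries, among them those of the wild-type tissues and between the knockouts, had no replicates in the deposited table. The comparisons of both knockouts had a lone wild-type library on the other side. Variation between mice was therefore not measured in these comparisons, and the counts are given as deposited.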

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

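All tests of explanations in this part were chosen after the results had been seen. The granulocyte list moved in opposite directions in the organs, since its median difference from wild-type was 2.29 and 3.15 in MPL−/− and TPO−/− marrow and −0.90 and −2.21 in spleen. The knockout effect in spleen minus that in marrow was −3.86, and 17 of 19 genes were higher in knockout marrow and lower in knockout spleen on the mean log2 CPM of both knockouts, the exceptions being Gfi1 and Mmp9, while Cebpe was also higher in spleen by the fitted fold (0.77). In MPL−/− spleen alone 11 of the 19 were lower and 8 higher than in wild-type (Mpo 370 against 336 CPM), so the opposite movement of single genes rested in part on TPO−/− spleen. In the test of that difference 0 of the 19 genes passed over all genes and 13 adjusted over the list alone, and fry gave the list an adjusted p of 0.211. For the calls between tissues, and not for this granulocyte difference, the 6 libraries were split into groups of 3 in 10 ways. The split by tissue called 3238 genes and the highest other 0, so 1 of 10 called as many, and 10 splits are too few for a share under 0.05. The other splits also leave much of the tissue difference in the spread, which makes calls unlikely, so they cannot be used to judge the split by tissue.

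Against wild-type, Mpl was lower in the libraries labelled TPO−/− (86 reads in marrow, 3 in spleen), while it was read at 0.755 and 1.63 times the wild-type level in those labelled MPL−/−. An exchange of the knockout labels goes with these levels and stays open: genes standing apart within 10 Mb, without Mpl, Thpo and Chrd, numbered 5 near Mpl in the libraries labelled MPL−/− (1.61 expected) and 7 near Thpo in those labelled TPO−/− (3.13 expected), against 3 (1.58 expected) and 4 (3.18 expected) at the other locus. The lowest p adjusted over these 4 pairs was 0.091. A gene stood apart if it was at least 2-fold above, or below, both other genotypes of the same tissue, in marrow and in spleen alike. No minimum CPM was set. Of 115 genes read in the libraries labelled TPO−/− alone, 2 lay within 50 kb of Thpo (Chrd and Thpo itself) against 0.031 expected, which goes with the labels as given but was found from the same reads and rests on how the targeted allele is read, which the labels do not give. Fewer stem cells and megakaryocyte-lineage cells in the libraries labelled TPO−/− may account for part of it, since 10 of 39 stem cell and megakaryocyte genes in marrow and 3 of 39 in spleen were lower by at least as much as Mpl (−3.07 and −5.44), whereas their medians were −1.86 and −2.20. In the libraries labelled MPL−/− the same genes were lower as well (medians −1.46 and −0.92) while Mpl was at −0.40 and 0.70, so that loss of these cells did not go with Mpl in both labels. Reading of a targeted Mpl allele in the libraries labelled MPL−/− (260 reads in spleen) cannot be told apart from intact Mpl, because counts per gene do not place reads in exons, and the loss of thrombopoietin as a cause of fewer Mpl-bearing cells stays open, untested.

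In knockout spleen, T and NK cell genes were higher (median 2.80) and DNA replication genes lower (median −0.98) than in 1 wild-type library, by size of fold, since the 1686 calls of the test fell to 359 without MPL−/− spleen and 0 without TPO−/− spleen. A lower share of Lin−cKit+ cells with all other cells raised alike was argued against as the whole cause. In 2 of 2 lists of other cell types (B cell and macrophage) the upper quartile, 0.68 and 0.82, was below the lower quartile of the T and NK cell list, 2.47. The B cell list also holds the early B cell genes Igll1, Vpreb1 and Vpreb3, so it cannot be taken as cells without cKit alone, and the argument rests on the macrophage list. Kit itself was lower in both knockout spleens than in wild-type spleen, so a lower share as part of the cause stays open. Without globin, immunoglobulin and mitochondrial genes, 96.6% of the 2424 genes at least 2-fold apart were still so. This removal cannot decide whether counts taken up by those genes matter, because TMM scaling was applied before and after it. In the spleen libraries immunoglobulin genes took 3.82% to 9.76% of the counts, mitochondrial genes 2.26% to 2.69% and globin genes at most 0.435%. T cells among the selected cells, past the lineage depletion and the cKit beads, stay open as an explanation of the T cell genes alone, with Cd3e at 162 and 257 CPM and Cd8a at 368 and 469 CPM in the knockout spleens. So does a change of the progenitors themselves, and neither was tested on single cells.

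By the same rule 144 genes stood apart in both libraries labelled MPL−/−, each against the other genotypes of its own tissue. Of these, 10 lay together on chromosome 17 between 20 and 30 Mb, against 1.89 expected. Without a minimum CPM the 144 include genes with few reads, such as Sox17 at 0.472 and 0.947 CPM in MPL−/− marrow and spleen. Chance position of single genes was argued against, since a window as full was held by 0.3% of 1000 shuffles of gene positions, with the observed case counted in. The shuffles moved each gene alone, so they cannot exclude neighbours that vary together. Gm10505, AC125141.3 and Grm4, for example, lie side by side between 27325035 and 27521403. Reads of a variant copy counted for a processed pseudogene were argued against as the whole cause, since 4 of the 5 genes of the window that were higher in those libraries are no pseudogenes. Among the 5 lower genes it stays open for Atp6v0c, which fell from 62.3 to 23.2 CPM in marrow and from 53.4 to 12.1 CPM in spleen. Atp6v0c-ps2 rose from 0.685 to 110 CPM and from 0.328 to 36.7 CPM. For the other lower genes it was not tested, and AC122821.1 among them is itself a processed pseudogene, at 1.74 CPM in wild-type against 0.172 CPM in MPL−/− marrow. Around Mpl, 5 of the 144 genes lay within 10 Mb, against 1.61 expected. A stretch from another strain in these mice stays open, since counts per gene hold no sequence and it was not tested.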

How the results depend on the processing

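The edgeR tests, the size rule and the alternatives without a block, with a term for the knockout label, with another prior count and with total counts were chosen after seeing the data; the others were planned. By size of fold, no comparison's total of genes moved by over 1.5 times under any alternative, though single directions did (925 lower in spleen became 1407 without wild-type spleen, and 217 higher in MPL−/− than TPO−/− marrow became 127 without globin, immunoglobulin and mitochondrial genes), with ranges on leaving out a library of 1852 to 2874 between tissues, 1434 to 2127 for knockouts over tissues, 1472 to 2041 in marrow, 2458 to 2640 in spleen and 1621 to 1982 for the difference of effects. The tested counts moved. For knockouts over tissues (1402) they were 2299 without the filter, 3456 with DESeq2 and 0 without the tissue block, and 102 to 1599 on leaving out a library, with 102 without wild-type spleen, 161 without MPL−/− spleen, 546 without TPO−/− spleen, 677 without TPO−/− marrow and 783 without MPL−/− marrow. Between tissues (3238) the count was 899 without the genotype block and 557 to 6898 on leaving out a library, with 557 without MPL−/− spleen, 672 without MPL−/− marrow, 6252 without wild-type spleen and 6898 without wild-type marrow. In marrow (174) it was 88 with DESeq2 size factors, 1306 without the filter, 0 with a filter of 1 CPM in 2 libraries, 438 without globin, immunoglobulin and mitochondrial genes, 1550 with DESeq2, 108 with limma-voom and 2385 with a term for the knockout label, and 0 to 1066 on leaving out a library, with 1066 without MPL−/− marrow, 300 without TPO−/− marrow, 102 without wild-type spleen and 0 without either knockout spleen. In spleen (1686) it was 2737 without the filter, 3032 with DESeq2, 4532 with the label term and 0 to 2247 on leaving out a library, with 359 without MPL−/− spleen and 0 without TPO−/− spleen. For the difference of effects (0) it was 173 without the filter, 322 with DESeq2, 1040 with the label term and 0 to 131 on leaving out a library, with 131 without MPL−/− marrow and 9 without TPO−/− marrow. Which direction had more genes changed as well under some of these, as given with the comparisons. The cause was not tested. A library left alone on its side was assumed to vary like the others. Among named genes 3538 values kept their side of the threshold, 909 no longer passed and 5 newly passed, and among gene lists 479, 152 and 4. No named gene that passed in the main fit or the alternative reversed direction, and no list called in the main fit did. Direction was not compared for genes that passed in neither fit or for lists not called in the main fit. Spleen and marrow were paired by genotype, no analysis paired by mouse was possible because the columns carry no mouse numbers, and the planned tests of 1 library against 1 and the block for mouse were not run, as each group had 1 library. The alternative for FPKM tables was not needed. Depth limits low genes, since 3 counts correspond to 0.126 to 0.189 CPM.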

Other observations

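Immunoglobulin variable genes differed widely from library to library. Igkv1-99 stood at 195 CPM in wild-type marrow and at most 54.4 CPM elsewhere, while Ighv5-4 stood at 336 CPM in MPL−/− spleen and at most 45.4 CPM elsewhere. Immunoglobulin genes took 9.76% of the counts in MPL−/− spleen and 0.398% in TPO−/− marrow. Globin genes took 1.13% of the counts in TPO−/− marrow and 0.0541% in wild-type marrow. Hba-a1 was at 5360 CPM and Alas2, of haem synthesis, at 420 CPM in TPO−/− marrow, where the erythroid regulators Klf1 (81.6 CPM) and Gata1 (42.6 CPM) were below wild-type (236 and 176 CPM). Globin and Alas2 did not pass the test of knockouts against wild-type (adjusted p of 0.135 for Hba-a1 and 0.219 for Alas2), and in MPL−/− spleen Hba-a1 was at 353 CPM against 311 CPM in wild-type spleen.

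Among mast cell and basophil proteases, Mcpt4 and Tpsb2 were read mainly in wild-type spleen, with Mcpt4 at 21 CPM there and at most 0.884 CPM in the other 5 libraries, and Tpsb2 at 9.61 CPM there and at most 0.316 CPM in the others. Others were not: Cpa3 was at 68.6 CPM in wild-type marrow and 73.7 CPM in wild-type spleen, Mcpt8 at 115 and 25.5 CPM, and Prss34 at 298 and 40.0 CPM. Immediate early genes were highest in wild-type spleen for Egr1 (1440 CPM against at most 535 CPM) and Atf3 (162 CPM against at most 46.8 CPM), while the heat shock genes Hspa1a and Hspa1b were highest in MPL−/− spleen, at 195 and 378 CPM. Plasma cell Jchain was at 6810 CPM in MPL−/− spleen and 97.5 CPM in TPO−/− marrow. Il6 was at 10.4 CPM in wild-type marrow against 3.35 and 0.252 CPM in the knockout marrows.

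Ndufs5, a subunit of respiratory complex I on chromosome 4, stood at 6.09 and 3.91 CPM in MPL−/− marrow and spleen and between 27.5 and 36.3 CPM in the other 4 libraries. Its pseudogene BC002163 stood at 28.0 and 16.2 CPM in the MPL−/− libraries and at most 0.328 CPM in the others. The sum of both was 32.4, 34.1 and 35.0 CPM in wild-type, MPL−/− and TPO−/− marrow, and 36.7, 20.1 and 27.6 CPM in spleen. Xist stood between 287 and 726 CPM and the Y-linked Ddx3y between 49.0 and 93.4 CPM in the 6 libraries.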
